A study of Mus musculus with 8 samples.

How the data were processed

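RNA was measured by sequencing in 8 mouse retinas, 4 from wild-type mice (WT) and 4 from mice expressing human transferrin (TG), each taken 4 days after a detachment made by injecting sodium hyaluronate under the retina. Per the labels' protocols, total RNA was selected for polyadenylated transcripts and made into strand-marking libraries. All mice carry the label C57Bl/6J. The WT group held 3 males and 1 female and the TG group 2 males and 2 females. The WT group held 3 right and 1 left eye, and the TG group 2 of each. The labels do not say outright that each retina came from a separate mouse, so p-values measure the spread between these samples.

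The deposited table lists 56465 features with coordinates on mm10 (GRCm38), of which 25972 carry a gene symbol and 30493 do not. Its values are DESeq2-normalized read counts, a signal scaled by the authors with 1 size factor per library, per the file headers and the submitters' processing notes. Those notes name FastQC, Picard, SAMtools, STAR 2.4.0 and DESeq2. The counting tool, its strand setting and the annotation release are not given in the sources used here. Reads of overlapping, antisense or near-identical genes therefore could not be told apart in every case. Each column proved to be whole multiples of its smallest positive value, with 100% of values within 0.01 of a whole read, so reads were recovered. The totals ran from 61535690 to 75866423 reads per library. No 2 libraries were near-copies of each other, since the lowest chi-square per feature between any pair was 58.1. The number of sample columns left unmapped was 0.

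The main test was limma 3.58.1 (R 4.3.3) on log2(normalized value + 1), with a trended prior variance, for the 19798 features with a mean of at least 10 over all 8 samples. P-values were adjusted by the Benjamini-Hochberg method, and 0.05 was the threshold for adjusted p. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. Count tests on the recovered reads, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0, were alternatives. Errors beside log2 fold changes are standard errors, and errors beside group values are standard deviations. Intervals are 95% and two-sided. The median standard error of a log2 fold change was 0.30, and 0.16 for features with a mean of at least 1000. A count of 0 was read against a floor of 3 reads per library, which covers counting error only.

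A set of 36 gene lists was fixed before the data were examined, and 35 of them were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 35. The other list, of sex-linked genes, only checked the labels. Camera with an estimated correlation and fry, which asks whether a list's genes move 1 way (or, mixed, either way) without comparing them with other genes, were also run. The estimated correlation was run under each alternative too, which was added after the data were seen. A list member is the feature of that symbol with the highest mean.

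The genes named were set by a rule fixed at the same time. It took Trf, Tfrc, Fth1, Ftl1, Slc40a1, Cp, Hmox1, Gfap and Aif1, among others, whatever their test. Some genes that the rule takes are not reported here. It took up to 10 genes per direction with the largest change among those past the threshold with a mean of at least 50 and no overlap between groups, leaving out symbols of predicted genes, Riken clones and pseudogenes. Where fewer than 5 passed in a direction, it took the 5 with the smallest p, given as values that did not pass. It also took up to 4 members of each list, those with the smallest p, of which a part is named. Gm16867, Gm19554, Entpd4 and the feature labelled Loxl2 and Mir6950 fall outside the rule and were chosen after their values were seen. So were Ttr, Rpe65, Mbp, Crybb2, Hbb-bs and Hba-a1, which are given per library as markers of other tissues.

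Alternatives changed 1 choice at a time: TMM, upper-quartile or quantile scaling, a pseudocount of 0.5 or 5, no filter or a minimum mean of 50, sex or eye as a term, males only, the variance model, array weights, the count tests, and leaving out each library. After the data were seen, leaving out WT 3 and TG 6 together and a pigment epithelium score as a term were added. The procedure was tested on simulated counts for the TG against WT comparison, with the libraries' own depths, means and dispersions, over 19264 features. It recovered 52% of 100 features changed 2-fold and 83% of 100 changed 4-fold, all drawn from features with a mean of at least 50. Both sets were changed in the same simulated data, which makes the adjusted threshold easier to pass. These rates therefore do not hold for lower features or where few features change. It called 12 unchanged features. In simulated data with no change it called 1 feature and 0 lists. Features were drawn independently, so the simulation held no correlation within lists and does not test the preset correlation. In the data the estimated correlation was 0.67 for the microglia and macrophage list. With the microglia and macrophage list shifted by 1 on the log2 scale, that list passed, and so did 1 other, complement, which shares members with it. Annotation for named loci came from GENCODE M21 on GRCm38. Python 3.11.15 and matplotlib 3.10.9 drew the figures.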

Results

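Messenger RNA was profiled in 4 detached retinas of WT mice (replicates 3, 4, 5 and 7) and 4 of TG mice (replicates 2, 5, 6 and 8), collected 4 days after detachment. TG mice express human transferrin, the iron carrier of blood plasma. The series title states the purpose as the effect of transferrin during retinal detachment, and TG against WT is the 1 comparison of its design. Libraries held 68433927 to 75866423 counted reads in WT and 61535690 to 70540242 in TG. Mitochondrial features took 21.9% to 27.5% of reads in WT and 20.4% to 22.3% in TG. Xist, which is transcribed from the inactive X chromosome, had 1739 to 2032 normalized reads in the 3 libraries labelled female and 0 to 16.6 in the 5 labelled male. The Y-linked gene Ddx3y had 412 to 691 normalized reads in the males and 0 in the females, so sex labels and reads matched in all 8 libraries. With sex as a term beside genotype, limma called 5 genes higher and 1 lower in males.

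Of 19798 features, 1 was higher and 1 was lower in TG at an adjusted p under 0.05 (limma). The lower one, Gm16867, lay at 1981 to 3617 normalized reads in the WT libraries (3058 ± 765, SD, n = 4) and at 0 in all 4 TG libraries (adjusted p = 7.0e-09). Against a floor of 3 reads per TG library, it was at least 1025-fold lower in TG. It is annotated as a protein-coding gene on the minus strand of chromosome 14, from 69363504 to 69503365 in the deposited table (mm10), and it overlaps Entpd4 and Gm21451, an unprocessed pseudogene. Strand and copy assignment were not stated for the counting, so its reads carry that uncertainty. The higher one, Gm19554, is a long intergenic noncoding RNA gene on chromosome 12, from 105899840 to 105902022. It lay at 108 to 284 in TG (201 ± 87.1, SD, n = 4) and at 0 to 7.2 in WT (2.32 ± 3.38, SD, n = 4). Its log2 fold change was 6.38 ± 0.81 (SE; adjusted p = 0.024, limma). The Gm19554 call was lost without WT 4, WT 5 or any 1 of the TG libraries (adjusted p from 0.051 to 0.32 without them), and with sex as a term (adjusted p = 0.059), a pseudocount of 0.5 (0.078), no low-value filter (0.061), a minimum mean of 50 (0.090), no variance trend (0.14), the pigment epithelium score as a term (0.052) or males only (0.39). Its log2 fold change stayed between 5.99 and 6.999 without any 1 library, and was 6.52 with sex as a term and 5.91 with males only.

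**Figure D1:**
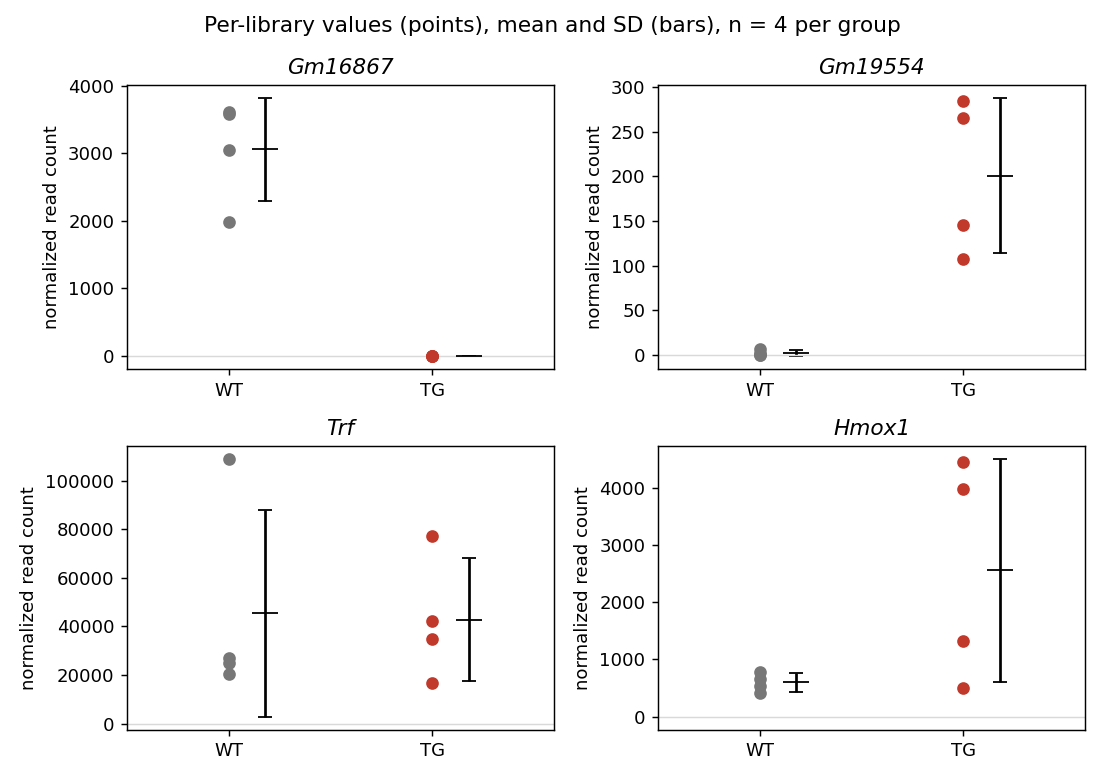
Normalized read counts of Gm16867, Gm19554, Trf and Hmox1 in each library (points; linear axes), with the mean and SD of 4 libraries per group (bars). Gm16867 is at 0 in the 4 TG libraries, Gm19554 is at 108 to 284 in TG and at most 7.2 in WT, and the groups overlap for Trf and Hmox1.

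Among symbols that the naming rule allows, with a mean of at least 50, the 5 genes with the smallest p in each direction did not pass the limma threshold. Their groups did not overlap, except for Dnah17. Fndc1, a fibronectin domain gene on chromosome 17, had 98.6 ± 13.9 normalized reads in WT and 315 ± 33.2 in TG (SD, n = 4 each; adjusted p = 0.11, limma). Dynlt1b, a dynein light chain gene on the same chromosome, had a log2 fold change of 1.28 ± 0.21 (SE; adjusted p = 0.21), which passed without WT 3 (adjusted p = 0.025). Nnt, the mitochondrial transhydrogenase, in which the C57Bl/6J strain is known to carry a deletion, had 207 ± 59.2 in WT and 484 ± 72.7 in TG. The breeding history of the mice is not given in the sources used here. That limits the reading of Gm16867, Gm19554 and Nnt alike, and of Fndc1 and Dynlt1b, which start at 7738568 and 6430112. Cd36, a scavenger receptor and fatty acid transporter, had 101 ± 10.8 and 288 ± 85.9 (SD, n = 4 each). H2-K1, a class I histocompatibility gene, also on chromosome 17 (start 33996013), had a log2 fold change of 0.84 ± 0.18 (SE). The missing breeding history limits its reading too. Log2 fold changes were negative for Wdr31 (-0.69), Nkd1, a Wnt pathway inhibitor (-1.004), Dpf3 (-0.65), Crnde (-1.77) and the axonemal dynein gene Dnah17 (-4.38), none of which passed with limma. The groups overlapped for Dnah17, with 12.9 normalized reads in WT 4 and 15.9 in TG 5. At an unadjusted p under 0.05 there were 918 features, 4.64% of those tested. The groups did not overlap for 500 features, 2.53%, where chance gives 2.86%. edgeR on the recovered reads called 1 higher and 1 lower, with 816 at an unadjusted p under 0.05, while DESeq2 called 9 higher and 7 lower, among them Fndc1, Dynlt1b, Nnt, Cd36, H2-K1, Crnde and Dnah17, with 1057 at an unadjusted p under 0.05.

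Mouse Trf, the nearest measured gene to the human transgene, had 45336 ± 42549 normalized reads in WT and 42729 ± 25332 in TG (SD, n = 4 each). Its log2 fold change was 0.09 ± 0.49 (SE; adjusted p = 0.99, limma), with a 95% interval from -0.98 to 1.15. The human transcript was not analysed here, and mouse Trf checks the genotype labels only as far as human reads align to it. WT 3 held 109021 normalized Trf reads against 20296 to 26945 in the other WT libraries, and without WT 3 the log2 fold change was 0.63. The fold change turned negative without WT 4 (-0.18), WT 5 (-0.04), WT 7 (-0.07) or TG 2 (-0.27), and with both count tests.

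No gene of iron handling passed over all genes. Of 37 measured members of the iron uptake, storage and export list, 20 lay higher and 17 lower in TG, 0 passed over all genes or adjusted over the list alone, and the list did not pass (adjusted p = 0.64, camera). Hmox1, which breaks down haem and releases iron, had 598 ± 160 normalized reads in WT and 2559 ± 1948 in TG (SD, n = 4 each). Its log2 fold change of 1.66 ± 0.54 (SE) did not pass (adjusted p = 0.92, limma). The 4 TG values were 3984, 4441, 1315 and 495, so TG 8 lay within the WT range of 418 to 788. With males only (3 WT and 2 TG libraries), Hmox1 passed (log2 fold change 2.69, adjusted p = 0.00038), while with sex as a term over all 8 libraries it did not (2.07, adjusted p = 0.50). Tfrc, the transferrin receptor, had 378 ± 266 in WT and 151 ± 87.2 in TG. The ferritin subunit genes Fth1 and Ftl1 had log2 fold changes of 0.04 ± 0.13 and 0.32 ± 0.21 (SE). Slc40a1, the iron exporter ferroportin, stood at 0.19 ± 0.33 (0.08 to 0.28 without 1 library), the ferroxidase gene Cp at 0.13 ± 0.25 and Fbxl5, an iron sensor, at -0.48 ± 0.14, and none passed. In the ferroptosis and glutathione list, 11 of 23 members lay higher and 12 lower (adjusted p = 0.95, camera), and Ptgs2 stood at -1.41 ± 0.47 (SE). Slc7a11, a subunit of the cystine transporter, had 191 ± 55.4 normalized reads in WT and 435 ± 311 in TG (SD, n = 4 each), with 899 in TG 6. Its log2 fold change of 1.02 ± 0.39 (SE), 0.59 without TG 6, did not pass. Gpx4, a peroxidase that reduces lipid peroxides, stood at -0.35 ± 0.16 (SE) and did not pass either.

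Of 7 immune lists, 3 rose in TG at the preset correlation, those of microglia and macrophage, antigen presentation and interferon response, and none of the 3 passed with an estimated correlation (adjusted p = 0.77 each). Complement, cytokines and chemokines (adjusted p = 0.065 each), lymphocyte (0.66) and monocyte and neutrophil (mean -0.92; 0.19) did not pass. The microglia and macrophage list had 31 of 32 measured members higher in TG, with a mean log2 fold change of 0.44 (adjusted p = 2.1e-07, camera; adjusted p = 0.77 with an estimated correlation). Of its members 0 passed, over all genes or adjusted over the list alone. Ctss, a lysosomal protease, had 3263 ± 345 normalized reads in WT and 5120 ± 1461 in TG (SD, n = 4 each). Siglech had 171 ± 43.2 and 305 ± 42.5, Laptm5 had 526 ± 189 and 959 ± 390, and the lipid receptor gene Trem2 had 411 ± 122 and 664 ± 290. Aif1 had a log2 fold change of 0.39 ± 0.35 (SE), and 0.17 to 0.69 without 1 library. The antigen presentation list had 12 of 13 members higher and a mean of 0.49 (adjusted p = 6.1e-06, and adjusted p = 0.77 with an estimated correlation). Its members H2-K1 and B2m passed when adjusted over the list alone (adjusted p = 0.0056 and 0.041) but not over all genes. For H2-K1 the limit from the breeding history, given above, holds here too. Tap2 and Psmb8, which supply peptides to class I molecules, stood at 0.47 ± 0.17 and 0.49 ± 0.20 (SE). The interferon response list had 19 of 21 members higher and a mean of 0.40 (adjusted p = 1.7e-04, and adjusted p = 0.77 with an estimated correlation), with Igtp at 0.58, Irgm1 at 0.58, Usp18 at 0.70 and Oas1a at 1.21, none of which passed. Without TG 5 the means were 0.13 for microglia and macrophage (adjusted p = 0.028), 0.20 for antigen presentation (adjusted p = 0.018) and 0.15 for interferon response (adjusted p = 0.28), while without TG 8 they were 0.84, 0.78 and 0.61. With males only the means were 0.98, 0.85 and 0.72, and with array weights the microglia and macrophage mean was 0.67. The interferon mean was also 0.63 without WT 3 and TG 6.

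Of 7 lists of retinal neurons and glia, 2 rose and 1 fell at the preset correlation, and 0 passed with an estimated one (adjusted p = 0.77, 0.77 and 0.80). The rod photoreceptor list fell, with 26 of 36 members lower in TG and a mean log2 fold change of -0.21 (adjusted p = 7.1e-04, camera; adjusted p = 0.80 with an estimated correlation). Prom1, needed for outer segment discs, had 30318 ± 4247 normalized reads in WT and 21398 ± 3917 in TG (SD, n = 4 each), and the channel gene Cngb1 had 54370 ± 4188 and 40684 ± 9019. Rp1 and Cdhr1 stood at -1.08 ± 0.39 and -0.74 ± 0.29 (SE). The bipolar cell list rose, with 14 of 16 members higher and a mean of 0.25 (adjusted p = 2.7e-04, and adjusted p = 0.77 with an estimated correlation), among them Gpr179 (0.34), Pcp2 (0.30) and Bhlhe23 (0.37). The Mueller glia list rose, with 13 of 16 members higher and a mean of 0.17 (adjusted p = 0.0075, and adjusted p = 0.77 with an estimated correlation). Apoe, a lipid carrier, passed when adjusted over that list alone (log2 fold change 0.57 ± 0.15, SE; adjusted p = 0.037), and Rlbp1, Car14 and Dbi stood at 0.60, 0.42 and 0.22. Without TG 5 the rod mean was -0.16 (adjusted p = 0.087) and without TG 8 it was -0.14. Without TG 8 the bipolar mean was 0.05 (adjusted p = 0.27), while without TG 6 it was 0.43. The Mueller glia call was lost without TG 8 (0.05), WT 5 (0.06) or TG 2 (0.07), and its mean was 0.32 without WT 7, 0.40 without TG 6, 0.36 without both WT 3 and TG 6, and 0.48 with males only. Lists for cone photoreceptor (adjusted p = 0.11; Opn1mw at -0.51), amacrine and horizontal cell (0.065; Slc32a1 at 0.44), ganglion cell (0.30; Stmn2 at 0.28) and reactive gliosis (0.75; Nes at -0.67) did not pass. At the preset correlation, the reactive gliosis list (mean -0.07) passed without TG 5 (-0.42, adjusted p = 0.0059) and, with the opposite sign, without TG 8 (0.41, adjusted p = 0.0011) and with males only (0.61, adjusted p = 1.4e-06). With an estimated correlation these fits gave adjusted p = 0.98, 0.57 and 0.38, and none passed. The ganglion cell list passed at the preset correlation without TG 5 (0.17, adjusted p = 0.0014) or WT 7 (0.18, adjusted p = 0.012), but not with an estimated one (adjusted p = 0.98 and 0.73). Gfap, the filament gene of reactive glia, had 2910 ± 917 in WT and 2110 ± 1395 in TG (SD, n = 4 each).

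Antioxidant, cell cycle and glycolysis lists rose and the immediate early list fell at the preset correlation, and none passed with an estimated one (adjusted p = 0.62 for antioxidant response and 0.77 for the others). Of 23 antioxidant response genes, 19 lay higher in TG, with a mean log2 fold change of 0.21 (adjusted p = 9.7e-04, camera; adjusted p = 0.62 with an estimated correlation). Prdx6, a peroxidase, had 12798 ± 789 normalized reads in WT and 18317 ± 1845 in TG (SD, n = 4 each) and passed when adjusted over the list alone (adjusted p = 0.020), though not over all genes. Mt1 and Srxn1 stood at 0.37 ± 0.21 and 0.27 ± 0.15 (SE). The cell cycle list had 16 of 21 members higher and a mean of 0.37 (adjusted p = 0.0054, and adjusted p = 0.77 with an estimated correlation), with Cdk1 at 26.1 ± 9.35 in WT and 66.1 ± 25.5 in TG (SD, n = 4 each) and Birc5, Rrm2 and Ccne1 at 1.59, 1.06 and 0.61. Glycolysis had 16 of 19 members higher, with a mean of 0.09 (adjusted p = 0.016, and adjusted p = 0.77 with an estimated correlation), including Eno1 (0.40), Gpi1 (0.27) and Ldhb (0.27), while the lactate transporter gene Slc16a1 stood at -0.49. The immediate early list had 13 of 16 members lower and a mean of -0.47 (adjusted p = 0.0052, and adjusted p = 0.77 with an estimated correlation), with Fos at -0.92, Klf4 at -1.40, Klf2 at -1.19 and Dusp1 at -0.81. The immediate early mean was -0.26 without WT 7 (adjusted p = 0.094), -0.28 without TG 6, and -0.39 without TG 8 (adjusted p = 0.10), -0.25 with array weights (adjusted p = 0.13), and 0.15 with males only (adjusted p = 0.44). The cell cycle mean was 0.16 without TG 5 (adjusted p = 0.080), 0.24 without TG 6 (adjusted p = 0.065), 0.23 without WT 7, 0.24 without WT 4, 0.77 without TG 8, 0.55 with sex as a term and 0.72 with males only. The glycolysis call was lost without WT 3 (mean 0.04, adjusted p = 0.18), TG 8 (0.07, 0.091), TG 6 (0.07, 0.065) or both WT 3 and TG 6 (0.02, 0.39). It was lost as well with sex as a term (0.06, 0.060), quantile normalization (0.06, 0.051) or males only (0.04, 0.44), and its mean was 0.14 with upper-quartile scaling. WT 7 had the highest Fos value, 4131 normalized reads, against 1341 to 1603 in the other WT libraries.

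**Figure D2:**
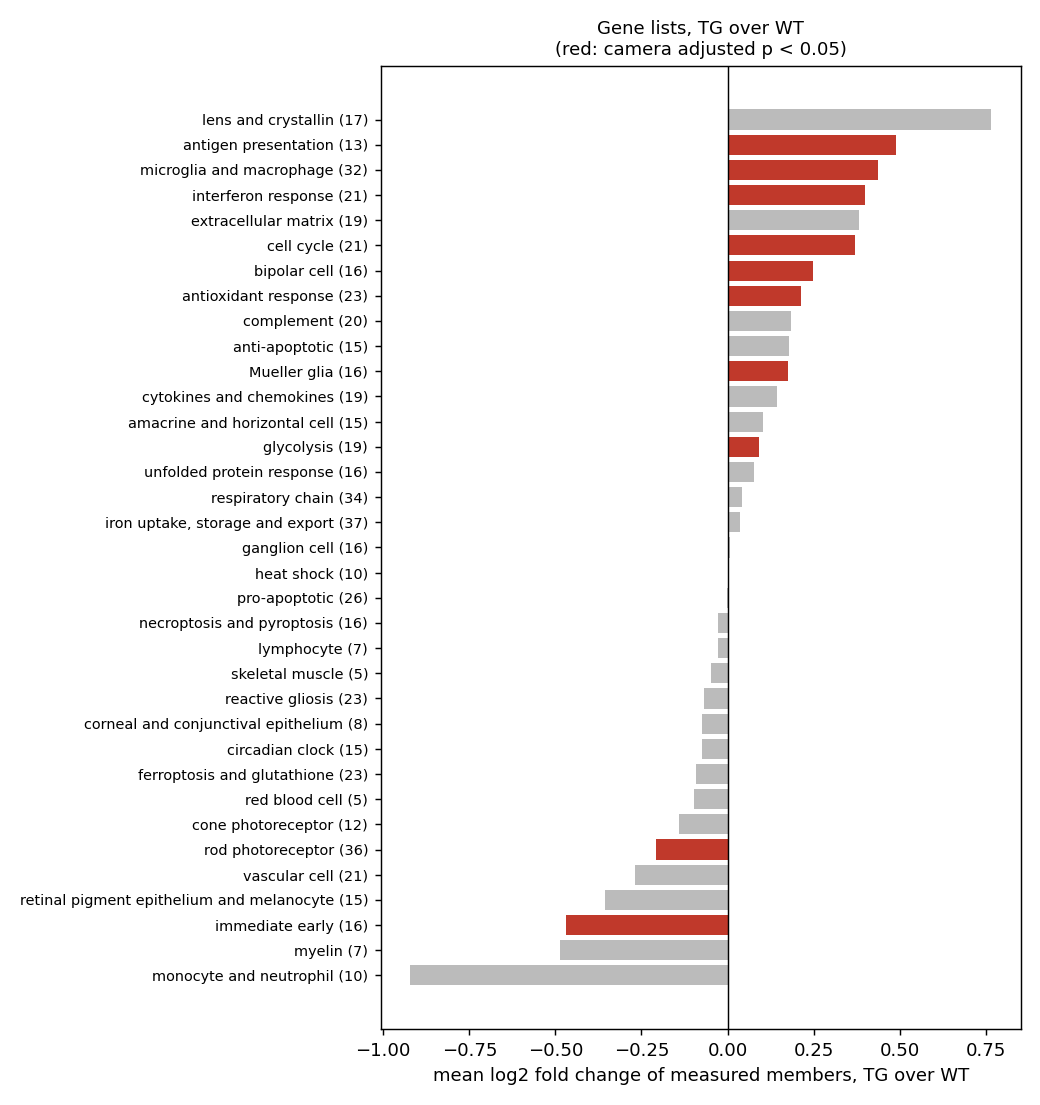
Mean log2 fold change (TG over WT) of the measured members of each of 35 gene lists, with the number measured in brackets; red bars are the 10 lists with a camera adjusted p under 0.05 at the preset correlation, 8 higher and 2 lower. With an estimated correlation 0 lists passed.

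None of the other 25 lists passed at the main settings. The highest mean was that of lens and crystallin genes (0.77; adjusted p = 0.096, camera; Crybb1 at 0.9995, and 0.34 to 1.88 without 1 library), followed by extracellular matrix (0.38; adjusted p = 0.066; Mmp2 at 0.90). Among lists of cell death, the mean was -0.0010 for pro-apoptotic genes (adjusted p = 0.95; Casp9 at -0.57). It was 0.18 for anti-apoptotic genes (adjusted p = 0.30), and 0.045 to 0.41 without 1 library. That list passed without TG 8 (0.41, adjusted p = 0.038) and with males only (0.64, adjusted p = 0.0019) at the preset correlation, though not with an estimated one (adjusted p = 0.25 and 0.32). The mean was -0.03 for necroptosis and pyroptosis (adjusted p = 0.95; Casp1 at 1.17), which with males only stood at 0.58 and passed at the preset correlation (adjusted p = 0.015; adjusted p = 0.55 with an estimated correlation). Complement (0.19; C1qc at 0.52), cytokines and chemokines (0.14; Csf1 at 0.88) and vascular cell (-0.27; Slco1a4 at -0.80) each had an adjusted p of 0.065. Monocyte and neutrophil genes had a mean of -0.92 (adjusted p = 0.19; S100a9 at -2.10), and -1.27 to -0.53 without 1 library. Respiratory chain had a mean of 0.04 (adjusted p = 0.11; Ndufb8 at -0.37), unfolded protein response 0.08 (0.28; Hspa5 at -0.38), heat shock 0.0029 (0.95; Bag3 at 0.44) and circadian clock -0.07 (0.95; Per3 at -0.72). For lymphocyte (mean -0.03, adjusted p = 0.66; Cd79a at -1.90), skeletal muscle (-0.05, 0.75; Acta1 at 1.16), corneal and conjunctival epithelium (-0.07, 0.88; Krt13 at 0.85), myelin (-0.49, 0.96; Mal at 0.34), necroptosis and pyroptosis, pro-apoptotic, circadian clock, and ferroptosis and glutathione, the mean was negative while camera gave the direction as up. Red blood cell genes had a mean of -0.10 (0.95; Hbb-bt at -0.30) and retinal pigment epithelium and melanocyte genes -0.36 (0.45; Mitf at -2.16).

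Several of these lists passed at the preset correlation when a setting or the set of libraries changed; the pigment epithelium score, and leaving out WT 3 and TG 6 together, were chosen after the data were seen. With an estimated correlation none of these calls held (adjusted p from 0.14 to 0.98). Extracellular matrix passed with sex as a term (0.58, adjusted p = 0.0038), array weights (0.68), no low-value filter (0.38), the pigment epithelium score as a term (0.55) and males only (1.31, adjusted p = 2.1e-12). It also passed without TG 8 (0.92), WT 7 (0.48), TG 6 (0.39), or WT 3 and TG 6 (0.50). Without 1 library the extracellular matrix mean ran from 0.025 to 0.92 (camera adjusted p up to 0.80). Complement passed with sex as a term (0.28), array weights (0.32), no low-value filter (0.19), the score (0.28) and males only (0.49), and without TG 8 (0.46, adjusted p = 4.1e-07), WT 3 (0.34), or WT 3 and TG 6 (0.27). Cytokines and chemokines passed with a minimum mean of 50 (0.30), sex as a term (0.27), array weights (0.28), the score (0.25) and males only (0.43), and without TG 8 (0.43), WT 3 (0.37), or WT 3 and TG 6 (0.23). Lens and crystallin genes passed with no low-value filter (0.80), eye as a term (1.07) and the score (1.20), and without WT 3 (2.29, adjusted p = 3.9e-08), TG 2 (1.72), TG 8 (1.40), or WT 3 and TG 6 (1.43). The vascular cell list passed with eye as a term (-0.36), without WT 3 (-0.32), WT 4 (-0.40) or TG 2 (-0.48), and, with the opposite sign, with males only (0.35, adjusted p = 0.0011). Without 1 library the vascular cell mean ran from -0.48 to -0.024 (camera adjusted p up to 0.92). The cone photoreceptor list passed with quantile normalization (-0.15), sex (-0.19) or eye (-0.21) as a term, and without WT 4 (-0.18), TG 6 (-0.24), or WT 3 and TG 6 (-0.23). Amacrine and horizontal cell genes passed with no low-value filter (0.10) and males only (0.30), and without WT 4 (0.16), WT 7 (0.24), TG 5 (0.10), TG 6 (0.35), or WT 3 and TG 6 (0.15). Respiratory chain genes passed without WT 3 (0.07), WT 5 (0.09) or TG 2 (0.11) and, with the opposite sign, with males only (-0.11). Pigment epithelium and melanocyte genes passed with eye as a term (-0.68) and without WT 4 (-0.68), red blood cell genes without WT 4 (-0.92, adjusted p = 7.6e-11), and monocyte and neutrophil genes without WT 3 and TG 6 (-1.15).

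Transcripts of neighbouring tissues varied between libraries within each group. The lens gene Crybb2 had 11187 normalized reads in WT 3 and 9561 in TG 6, against 1.9 to 2378 in the other 6 libraries. Myelin gene Mbp had 10093 in WT 3 and 224 to 492 elsewhere. Ttr, abundant in pigment epithelium, had 67791 in WT 3 and 30942 in TG 2, and the visual cycle gene Rpe65 had 7153 and 2698 there. Blood transcripts were lowest in WT 4, where the globin genes Hbb-bs and Hba-a1 had 1532 and 686 normalized reads, against 7878 to 22632 and 3336 to 9962 in the other 7 libraries. Without WT 4 the red blood cell list had a mean of -0.92 and passed at the preset correlation, though not with an estimated one (adjusted p = 0.40). Without WT 3 and TG 6, an alternative chosen after these values were seen, 1 feature was higher and 1 lower, and 16 lists passed at the preset correlation. Across all tested features, the mean correlation between libraries was 0.927 within groups and 0.927 between groups.

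**Figure D3:**
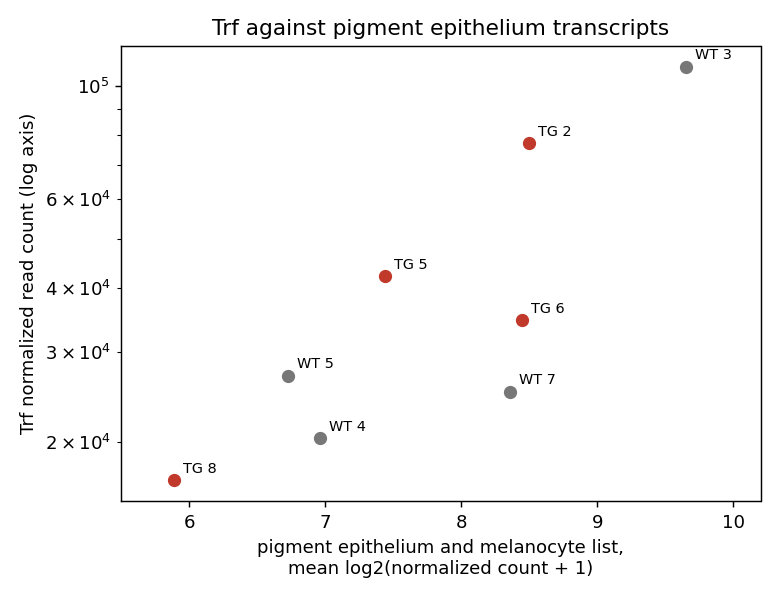
Trf normalized reads (log axis) against the mean log2(normalized count + 1) of the pigment epithelium and melanocyte list in each library, grey WT and red TG. WT 3 is highest on both axes (9.65 and 109021) and TG 8 lowest on both (5.89 and 16774).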

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

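The tests of Trf below were chosen after its values were seen. There were 167 sets of 4 libraries (84 genes in each group, less 1 set with all values at 0). Dixon's critical value of 0.829 would be passed by about 8.35 of them if they were independent and normally distributed. The values were normalized reads, not logs, and genes share libraries, so 8.35 is only a rough guide. In 20 sets, the gap of 1 library to its neighbour took most of the range, beyond that critical value. Of these, 9 concerned WT 3: Trf (109021 normalized reads against 20296 to 26945 in the other WT libraries), Crybb1 (385 against 14.8 to 54.3), Oas1a (353 against 30.6 to 67.2), Aif1 (728), Trem2 (593), Dynlt1b (1177), Casp1 (80.9), Psmb8 (1123) and Gpx4 (44491 against 34492 to 35380). WT 7 stood apart for Fos (4131 against 1341 to 1603), Dusp1 (721), Klf4 (471) and Slco1a4 (966), and WT 5 for Eno1 (211016). In TG, the library apart was TG 5 for Slc40a1 (112) and Hspa5 (11179), TG 8 for Birc5 (29.3 against 86.3 to 97.5) and Hbb-bt (2064), and TG 6 for Krt13 (30.9) and Slc7a11 (899 against 241 to 324). For the sex by genotype term, limma called 1 gene among all tested, which is not one of the genes named here, with 2334 at an unadjusted p under 0.05, and the WT group had 1 female.

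The spread of Trf may come from RNA of pigment epithelium rather than from genotype, as a hypothesis. Over the 8 libraries, Trf followed the mean of the pigment epithelium and melanocyte list (Pearson r = 0.83, permutation p = 0.010, adjusted 0.021; Spearman rho = 0.83, permutation p = 0.015, adjusted 0.031, exact, two-sided, 2 relations computed), and r was 0.54 without WT 3 and TG 8, the 2 farthest from the median. For the myelin list rho was 0.48 (permutation p = 0.24, adjusted 0.24) and r was 0.75 (permutation p = 0.024, adjusted 0.024), 0.51 without WT 3 and TG 6, so a myelin source stays open. Human reads counted on the mouse gene cannot come from WT mice, so they are argued against as the source of the spread among WT libraries, where the highest value was 5.37 times the lowest. In TG they were predicted to put every library above WT, and 2 libraries were out of place (WT 3 above every TG library, TG 8 below every WT library), 1 in each group. With the WT libraries themselves this far apart, that prediction cannot decide, so a part from human reads in TG stays open. A genotype effect on Trf beneath this spread stays open, since with the pigment epithelium score as a term the log2 fold change was 0.32 and did not pass.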

How the results depend on the processing

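The alternatives without WT 3 and TG 6 together, with the pigment epithelium score, with an estimated correlation and with fry were added to those fixed before the data were examined, the first 2 after the data were seen. No paired analysis was possible because the groups share only 1 replicate number. Gm16867 stayed past the threshold under every alternative run. The count of features higher in TG, 1, was 0 with a pseudocount of 0.5, no low-value filter, a minimum mean of 50, sex as a term, no variance trend, or the pigment epithelium score, 9 with DESeq2 and 0 to 2 without 1 library. The cause was not tested. Gm19554 had an adjusted p from 4.2e-15 to 0.39 over its alternatives. The count lower in TG, 1, was 3 with males only, 7 with DESeq2 and 1 to 2 without 1 library. With DESeq2 the calls included Fndc1, Dynlt1b, Nnt, Cd36, H2-K1, Crnde and Dnah17, and 2 of its 16 calls were those of limma. The lists past the threshold, 10, were 17 with males only, 16 without WT 3 and TG 6, and 0 with an estimated correlation, fry or fry mixed, and 10 to 15 without 1 library. With an estimated correlation, 0 lists passed under every other alternative fitted as well, a test chosen after the data were seen.

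Values that changed sign were log2 fold changes of genes and mean log2 fold changes of lists, and the cause was not tested. With upper-quartile scaling, the values were pro-apoptotic (0.046), necroptosis and pyroptosis (0.017), lymphocyte (0.0097). With quantile normalization, these stood at Fth1 (-0.056), pro-apoptotic (0.066), necroptosis and pyroptosis (0.11), lymphocyte (0.17), corneal and conjunctival epithelium (0.14), skeletal muscle (0.14). With a pseudocount of 5, the changes were pro-apoptotic (0.014), necroptosis and pyroptosis (0.041), lymphocyte (0.029), skeletal muscle (0.10). With no low-value filter, turned values were necroptosis and pyroptosis (0.075). With a minimum mean of 50, the values were pro-apoptotic (0.043), necroptosis and pyroptosis (0.058), corneal and conjunctival epithelium (0.26), skeletal muscle (0.64). With sex as a term, these stood at pro-apoptotic (0.042), necroptosis and pyroptosis (0.11), ganglion cell (-0.082), reactive gliosis (0.16), skeletal muscle (0.060), heat shock (-0.0078). With eye as a term, the changes were pro-apoptotic (0.0059), ganglion cell (-0.098), lymphocyte (0.057), heat shock (-0.0035). With males only, turned values were Gfap (0.34), Nes (0.18), Slco1a4 (0.057), ferroptosis and glutathione (0.051), pro-apoptotic (0.22), necroptosis and pyroptosis (0.58), reactive gliosis (0.61), lymphocyte (0.42), lens and crystallin (-0.52), retinal pigment epithelium and melanocyte (0.19), vascular cell (0.35), red blood cell (0.22), corneal and conjunctival epithelium (0.62), skeletal muscle (0.56), respiratory chain (-0.11), immediate early (0.15), circadian clock (0.13). With array weights, the values were Hbb-bt (0.26), pro-apoptotic (0.067), necroptosis and pyroptosis (0.16), ganglion cell (-0.029), reactive gliosis (0.18), lymphocyte (0.28), red blood cell (0.49), corneal and conjunctival epithelium (0.29), skeletal muscle (0.046). With edgeR on recovered reads, these stood at Trf (-0.059), pro-apoptotic (0.0082), necroptosis and pyroptosis (0.010), lymphocyte (0.00021), skeletal muscle (0.030). With DESeq2 on recovered reads, the changes were Trf (-0.086), pro-apoptotic (0.0062), necroptosis and pyroptosis (0.0091), skeletal muscle (0.026). Without WT 3 and TG 6, turned values were Cp (-0.097), Hbb-bt (0.12), pro-apoptotic (0.041), necroptosis and pyroptosis (0.066), ganglion cell (-0.12), lymphocyte (0.013), red blood cell (0.33), skeletal muscle (0.042), myelin (0.59), respiratory chain (-0.0047), heat shock (-0.032), circadian clock (0.016). With the pigment epithelium score as a term, the values were pro-apoptotic (0.016), necroptosis and pyroptosis (0.088), ganglion cell (-0.018), reactive gliosis (0.014), corneal and conjunctival epithelium (0.069), heat shock (-0.0085). Leaving out 1 library at a time turned the sign, within these ranges, for Cp (-0.073 to 0.35), Fth1 (-0.027 to 0.076), Hbb-bt (-1.34 to 0.13), Trf (-0.27 to 0.63), amacrine and horizontal cell (-0.099 to 0.35), circadian clock (-0.15 to 0.055), complement (-0.019 to 0.46), corneal and conjunctival epithelium (-0.75 to 0.57). The same held for cytokines and chemokines (-0.10 to 0.43), ganglion cell (-0.15 to 0.18), heat shock (-0.047 to 0.047), iron uptake, storage and export (-0.041 to 0.20), lens and crystallin (-0.23 to 2.29), lymphocyte (-0.53 to 0.20), myelin (-0.93 to 0.24). It held too for necroptosis and pyroptosis (-0.47 to 0.34), pro-apoptotic (-0.13 to 0.083), reactive gliosis (-0.42 to 0.41), red blood cell (-0.92 to 0.29), respiratory chain (-0.031 to 0.11), retinal pigment epithelium and melanocyte (-0.75 to 0.22), skeletal muscle (-0.18 to 0.31). Of 82 named genes not past the threshold, 44 moved by over 1.5 times or turned sign without 1 library. The standard error of a log2 fold change had a median of 0.30 over all features and 0.16 for those with a mean of at least 1000. Small changes of low features were therefore not detectable. Larger changes of higher features missed the threshold too, such as Dynlt1b (1.28, adjusted p = 0.21, limma) and H2-K1 (0.84, adjusted p = 0.92, limma). The few calls thus do not show that well-expressed genes were unchanged.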

Other observations

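The tests of depth, copies, neighbouring features, counts of genes and lists over splits, and the pigment epithelium score were chosen after the results were seen. Those of the 2 single lists and of on and off features were written before. For gene counts, 4 of the 35 splits of the 8 libraries into 4 and 4 gave at least as many features as the real 2, with 29 as the highest other, so chance cannot be excluded for the count. That split, picked as the highest, set WT 3, WT 5, TG 5 and TG 6 against the rest. Its count, many times the real one, may come from a structure of the samples, and what these libraries share was not tested. The smallest limma p of all features was reached by 1 of the 35 splits, the real one (3.5e-13 against 1.2e-09 at the lowest other), the fewest possible. That p is of Gm16867, and the measure was chosen after Gm16867 was seen, so it does not exclude chance. The count of on and off features below, written before, was matched by 14 of 35 splits. On meant at least 10 normalized reads in all 4 libraries of 1 side, and off at most 1 in all 4 of the other. That admits features far lower than Gm16867, so the count cannot decide whether chance gives a feature as strong. For lists at the preset correlation, 25 of 35 splits gave at least the real 10, up to 21, so chance cannot be excluded.

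The 0 counts of Gm16867 and the presence of Gm19554 in TG may reflect an inherited difference between the mouse lines near these loci. This is a hypothesis, and Nnt, Fndc1, Dynlt1b and H2-K1, which did not pass with limma, stay open in the same way. All mice carry 1 strain label. Depth argues against being the source, since at the lowest WT share the shallowest TG library would hold 1683 reads of Gm16867. The other features within 500 kb summed to 7404 normalized reads in WT and 6088 in TG (a difference of -1316 ± 688, SE), a sum led by Slc25a37 and R3hcc1. The overlapping gene Entpd4 lay at 91.1 to 711.7 in WT and 36.1 to 208.7 in TG (log2 fold change -1.56 ± 0.64, SE), and did not pass. Of 3 overlapping or near-identical genes, 2 (Entpd4b and Gm21451) have no feature under their own symbol in that sum. The sum does include a feature labelled Loxl2 and Mir6950 that starts at 69391201, within the spans of Gm16867 and Gm21451. Its mean was 216 in WT and 236 in TG. Reads assigned to copies, or left uncounted for aligning to several places, therefore stay open. Neighbouring features clustered among the 100 smallest p more than in any other split (33 pairs within 2 Mb, highest other 32). For the 200 and the 500 smallest p, counted within 1 Mb, 4 and 11 of 35 splits gave as many. The 3 counts differ in window as well as in number of features, and their results differ. An inherited segment therefore cannot be told apart from chance. Features on in 1 group and off in the other numbered 1 in the real split, and 14 of 35 splits gave as many (up to 4), while an effect of the transgene on Gm16867 was not tested.

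For the rise of the microglia and macrophage list, 11 of 35 splits gave a camera p as small (real 6.1e-09, lowest other 2.1e-44), and for antigen presentation 6 of 35 (3.5e-07 and 8.9e-18), so chance splits of libraries that differ in these genes stay open. With the pigment epithelium score as a term, the mean log2 fold change of the microglia and macrophage list went from 0.44 ± 0.498 to 0.58 ± 0.37 (SE between libraries), a rise of 32.9%. The score itself differed by -0.36 ± 0.91 (SE) between TG and WT. Neither goes the way that RNA of pigment epithelium needs, but both lie within the spread between libraries, so it stays open. A genotype effect remains a hypothesis that these 8 libraries do not separate from the spread between them.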
